A study of Homo sapiens with 18 samples.

How the data were processed

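Bulk RNA sequencing libraries were measured from 6 human neuroblastoma cell lines, with 3 libraries per line and 18 libraries in all. The parental line is a derivative of SH-SY5Y, a neuroblastoma line, that expresses the neurotrophin receptor TrkB. The 5 entrectinib-resistant lines, ER5, ER28, ER29, ER42 and ER47, were grown out of subcutaneous tumours of that line which had first responded to oral entrectinib in nude mice and had then regrown. Entrectinib is an inhibitor of the Trk receptors, ALK and ROS1. Per the labels' protocols, the mice received 60 mg/kg every 4 hours (ER5, ER28 and ER29) or every 6 hours (ER42 and ER47). The cultured lines were raised from 10 nM to 750 nM entrectinib and were kept at 200 nM for harvest. The labels give no drug for the parental culture. Resistance is therefore confounded with the presence of the drug, passage through a mouse and culture history.

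Per the labels' protocols, total RNA was extracted with a Qiagen AllPrep kit, and libraries were made with the KAPA RNA HyperPrep kit after enzymatic removal of ribosomal RNA. HiSeq and NextSeq sequencers were both used; which library ran on which is not given in the sources used here, so no batch could be tested. Per the submitters' processing notes, STAR 2.5.3, featureCounts, Subread 1.5.0-p1 and STAR-Fusion were used with the hg19 build. The tool that made the FPKM values, how the library totals were set and whether counting used the strand are not given in the sources used here. Values of antisense and overlapping genes, and of near-identical copies such as HSPA1A and HSPA1B, are therefore uncertain.

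The authors deposited FPKM values (fragments scaled for transcript length and library total) for 63657 Ensembl gene identifiers in each library, and each library had its own column. Gene symbols, gene types, chromosomes and gene order were taken from GENCODE v29 on GRCh38. Of the identifiers, 52514 (82.5%) were found in that annotation and 40039 (62.9%) carried a symbol there. Of the 19799 tested identifiers, 18862 (95.3%) were found, 16287 (82.3%) carried a symbol and 12795 were protein coding. Because the values were made on hg19, no coordinates are given.

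FPKM values are not read counts, so no count test was used. The values of low genes moved in steps, as single reads would, and the most common step ratio gave each library a depth between 1 and 1.97 times that of parental replicate 1. That ratio rested on 102 to 303 genes per library, of which 22.7 to 54.2% sat at the most common value. The FPKM summed to between 848024 and 1106282 per library, and the 10 highest genes took 21.5 to 39.8% of the sum. Between 16041 and 18265 genes reached an FPKM of 1. In 54 genes, of which 1 was protein coding, a library was listed at exactly 0 although the median over the libraries was at least 10. An exact 0 can therefore be a failed estimate, and such genes are described as listed at 0. Correlations of the log2 values across genes, which are not independent replicates, were 0.953 to 0.975 within lines and 0.892 to 0.964 between lines.

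Genes with an FPKM of at least 1 in at least 3 of the 18 libraries were tested. The values were transformed to log2(FPKM + 1), and 1 limma model with an intensity trend was fitted to all 18 libraries with 1 coefficient per line (R 4.3.3, limma 3.58.1, statmod 1.5.0). Tests were two-sided, and a gene was called at a Benjamini-Hochberg (BH) adjusted p under 0.05. A fold change is on the log2(FPKM + 1) scale and understates the change of low genes. Each resistant line was compared with the parental line. The mean of the 5 lines was compared with the parental line. That comparison took its error from the spread of libraries within lines. Its SE and p-values therefore do not measure how far the resistant lines vary among themselves. An F test compared the 5 resistant lines with each other. The dosing intervals were compared in a limma model of the 5 line means, since the replicate of an interval is the tumour-derived line. Genes called with the same sign in all 5 lines are described as shared. The labels do not say whether the 3 libraries of a line came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

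There were 24 gene lists and 4 lists of markers of other cell types. They included lists of Trk receptors and neurotrophins, other receptor tyrosine kinases, the IGF axis, ERK pathway output and feedback, the RAS-ERK core, noradrenergic identity, mesenchymal neuroblastoma identity, extracellular matrix, neuronal differentiation, cell cycle, MYC family and targets, ABC efflux transporters and apoptosis regulators. Others were hypoxia and glycolysis, cholesterol biosynthesis, lysosome, interferon response, integrated stress and unfolded protein response, Notch pathway, Wnt pathway, Eph receptors and ephrins, mitochondrially encoded transcripts, and immediate early and heat shock genes. The marker lists were for Schwann cell precursors and glia, fibroblasts, endothelium, and leukocytes and macrophages. Each list was tested with limma's camera at a preset correlation of 0.01, per line and for the mean of the 5 lines, with BH adjustment over the 168 tests. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it.

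The groups, the tests, the lists, the alternatives, apart from 3 added later, and the rule for named genes were fixed before the data were examined. The rule named the 12 shared genes with the highest and the 12 with the lowest mean fold. For each line it named the 4 highest and 4 lowest genes that were called against the parental line and, with the same sign, against each of the other 4 lines. It took the 5 highest and 5 lowest genes called between dosing intervals, or the 3 with the smallest p where none was called, and up to 4 members per list with the largest mean fold. Genes always included were NTRK2, NTRK3, ALK, ROS1, NGFR, IGF1R and others. Some genes that the rule named, and 1 list, are not reported here. Clone names, small RNAs, pseudogenes, XIST and Y-linked genes were not named.

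The procedure was tested on simulated data made from the real means and spreads of 19799 genes. Only 67, 67 and 66 genes were changed, by 0.5, 1 and 2 on the log2 scale. The changed genes had parental means over 1 on the log2(FPKM + 1) scale, and the noise was independent between genes. Per line, 43.3 to 61.2% of genes changed by 0.5 on the log2 scale were recovered, 85.1 to 89.6% of those changed by 1, and 93.9 to 97% of those changed by 2, with 7 to 13 false calls among 19599 unchanged genes. In the real data 35.5 to 52% of the tested genes were called per line. The simulated false calls and recoveries therefore do not carry over to the real lists of called genes, which may hold many more false calls. Recovery of shared genes was 31.3, 80.6 and 93.9% at these sizes, and recovery by the F test was 44.8, 86.6 and 90.9%. For the dosing intervals it was 0, 5.97 and 63.6%, so small differences between intervals were mostly beyond reach.

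The alternatives were a pseudocount of 0.1, no filter, a filter at an FPKM of 5, median-of-ratios scaling, quantile normalisation, no intensity trend, a log2 size limit of 1, the replicate number as a block, only the 6 libraries of each comparison, an estimated correlation in camera, line as a random block for the dosing intervals, and each library left out in turn. The lists were not tested with a library left out, without the intensity trend, under the size limit or on only 6 libraries. Ranges given for lists over the alternatives do not cover these settings. Another 3 alternatives were chosen after seeing the data. They were protein-coding genes only, removal of genes listed at 0 beside a median of at least 1, and removal of each library's trend with GC content and transcript length, which used the 95.3% of tested genes that had a reference transcript.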

Results

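Transcript levels were measured by RNA sequencing in the parental TrkB-expressing neuroblastoma line and in 5 entrectinib-resistant lines derived from its xenograft tumours, with 3 libraries per line. Relative depth lay between 1 and 1.97 times that of parental replicate 1. The first principal component of the 18 libraries held 30% of the variance and the second 12.6%. The question was which transcripts distinguished resistant lines from the line they came from, which of these changes the 5 lines had in common, and where the lines differed. Values are mean FPKM ± SD over 3 libraries, and folds are log2 differences ± SE from the limma model. The SE of a mean over the 5 lines reflects the spread of libraries within lines, not the spread between lines.

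NTRK2 (ENSG00000148053, chromosome 9), which encodes the drug's target TrkB, stayed among the abundant transcripts in every resistant line. It stood at 411 ± 9.86 in the parental line (n = 3) and at 248 ± 25.3 in ER5, 318 ± 28.1 in ER28, 200 ± 16.3 in ER29, 261 ± 30.6 in ER42 and 391 ± 39.9 in ER47. Its fold was -0.58 ± 0.08 over the 5 lines (limma, BH-adjusted p = 1.91e-05). NTRK2 fell in 4 lines, by 0.37 to 1.04 on the log2 scale, and in ER47 the fold of -0.08 ± 0.10 did not pass (limma, BH-adjusted p = 0.569). Under quantile normalisation the mean fold was -0.22, and NTRK2 in ER28 was no longer called (-0.10, BH-adjusted p = 0.354). The folds of NTRK2 in ER5 (-0.35), NTRK2 in ER29 (-0.52) and NTRK2 in ER42 (-0.43) were smaller there, and NTRK2 in ER47 turned to 0.33 (BH-adjusted p = 0.00289). Without ER28 replicate 2, NTRK2 in ER28 had a fold of -0.30 (BH-adjusted p = 0.0516). Over the alternatives its adjusted p ranged from 0.00401 to 0.354 (0.00289 to 0.855 for ER47).

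Transcripts of other members of the neurotrophin system rose in several lines. NTRK3 (TrkC) rose in ER28, ER29 and ER47, by 1.55, 2.16 and 1.10, from a parental level of 0.295 ± 0.136. NTRK3 in ER42 had a fold of -0.25 (BH-adjusted p = 0.201). It passed with a pseudocount of 0.1 (-1.09, BH-adjusted p = 0.0192) and under quantile normalisation (-0.42, BH-adjusted p = 0.0192), in a range of 0.0192 to 0.472 over the alternatives. NGFR, the low-affinity neurotrophin receptor, had a mean fold of 1.33 ± 0.18 and was called in every line except ER42. BDNF, a ligand of TrkB, rose in all 5 lines with a mean fold of 1.27 ± 0.11. Of the 6 tested members of the Trk and neurotrophin list, 4 rose and 2 fell in the mean of the 5 lines, the same adjusted over the list alone. The list as a whole was not called (camera, BH-adjusted p = 0.274). In ER28 that list was called higher (camera, BH-adjusted p = 0.0483; adjusted p = 0.424 with an estimated correlation). That call was lost with a pseudocount of 0.1 (0.0564), at a filter of FPKM 5 (0.199) and with the replicate number as a block (0.0539), in a range of 0.00915 to 0.424.

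ALK, another target of the drug, rose from 36.7 ± 0.483 to 76.5 in ER29, 63.1 in ER42 and 75.1 in ER47, and its mean fold was 0.66 ± 0.12 (limma, BH-adjusted p = 0.00034). In ER28 the fold was 0.07, with libraries at 43.1, 45.7 and 28.8 FPKM in replicates 1, 2 and 3. The call for ALK in ER5 (0.46, BH-adjusted p = 0.0262) was lost with no filter (BH-adjusted p = 0.0561), without parental replicate 1, 2 or 3 (BH-adjusted p = 0.0602, 0.0608 and 0.0523), and without ER5 replicate 2 (BH-adjusted p = 0.0748) or ER5 replicate 3 (BH-adjusted p = 0.0917), all in limma, where the alternatives ranged from 0.00698 to 0.0917. ROS1, the remaining target, was listed at 0 in all but 1 library, an ER5 library at 0.008. IGF1R, the receptor of insulin-like growth factors, fell in all 5 lines (mean -0.54 ± 0.07, BH-adjusted p = 1.73e-05), and under quantile normalisation its mean fold was -0.34.

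**Figure D1:**
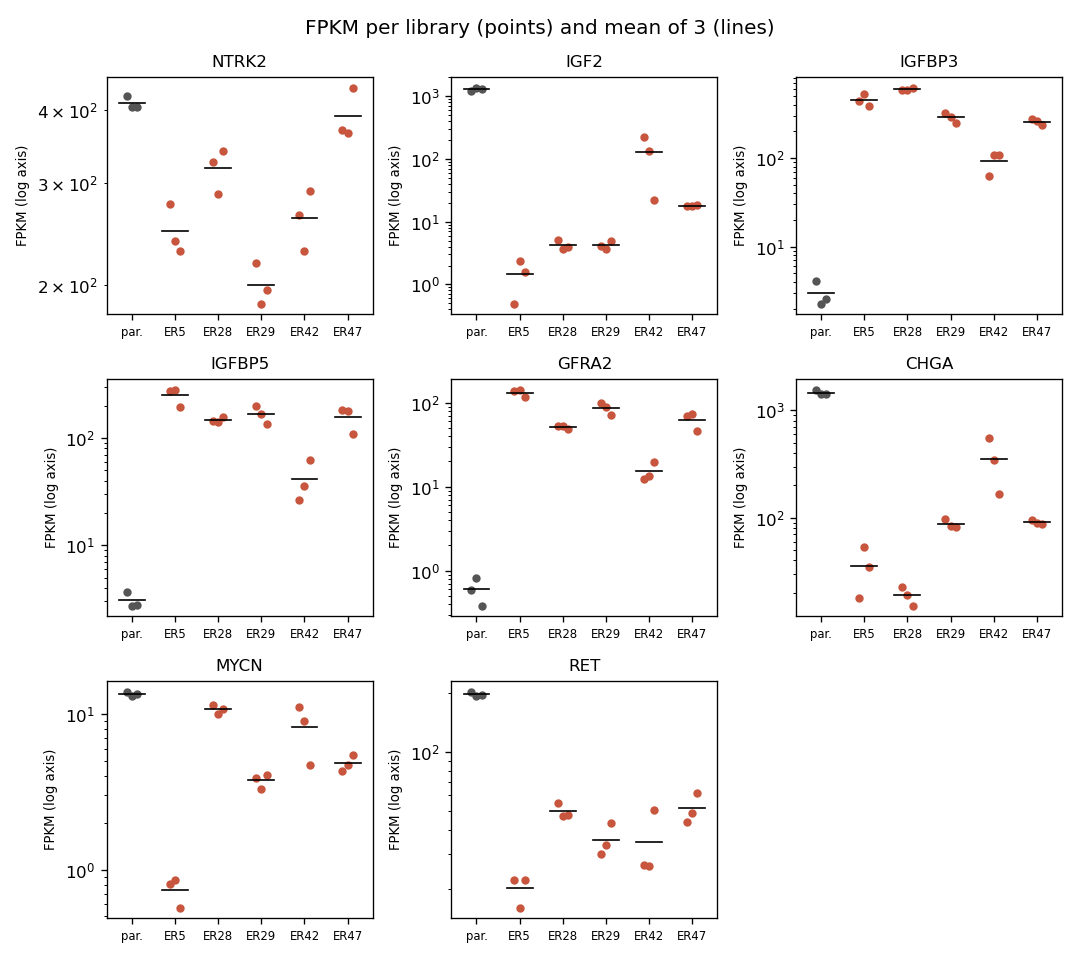
FPKM of 8 genes in each library (points) of the parental line (par.) and the 5 resistant lines, on log axes that start at different values, with horizontal lines at the mean of 3 libraries. IGFBP3 went from a mean of 3.00 in the parental line to between 92.4 and 594, IGF2 from 1290 to between 1.48 and 128, and NTRK2 stayed between 200 and 391.

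The shared genes with the highest and the lowest mean fold both belonged to insulin-like growth factor signalling. IGFBP3 (ENSG00000146674, chromosome 7), a secreted binding protein of these growth factors, rose from 3.00 ± 0.966 to between 92.4 ± 26.4 in ER42 and 594 ± 19.2 in ER28, a mean fold of 6.16 ± 0.15 (limma, BH-adjusted p = 6.79e-13). IGFBP5, another binding protein, rose by 5.00 ± 0.20. IGF2 (ENSG00000167244, chromosome 11), the ligand, stood at 1290 ± 81.4 in the parental line and dropped to 1.48 ± 0.937 in ER5, 4.24 ± 0.756 in ER28, 4.25 ± 0.588 in ER29, 128 ± 103 in ER42 and 18 ± 0.333 in ER47 (mean fold -6.98 ± 0.43, BH-adjusted p = 5.81e-09). Without ER42 replicate 1 the ER42 mean was 78.1. IGFBP2 had a mean fold of -1.61 ± 0.10. Because its members went both ways, the IGF axis list as a whole was not called, with 4 members higher, 4 lower and 12 tested, the same adjusted over the list alone (camera, BH-adjusted p = 0.925, direction up; median -0.04, mean 0.14).

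Among the other shared genes with high folds, GFRA2, the co-receptor through which neurturin signals to RET, rose from 0.599 ± 0.219 to between 15.2 ± 4.09 and 132 ± 13.8 (mean 5.16 ± 0.14, BH-adjusted p = 1.34e-12). RET itself fell from 197 ± 4.80 to between 20.1 and 51.4 (mean -2.43 ± 0.17, BH-adjusted p = 1.74e-08). The muscarinic acetylcholine receptor CHRM2 rose by 4.73 ± 0.23, while its relative CHRM3 fell from 87.9 ± 8.31 to between 0.654 and 2.21 (mean -5.24 ± 0.14, BH-adjusted p = 1.02e-12). The lower of these CHRM3 means, that of ER5, was 0.431 without ER5 replicate 2. The monoamine-degrading enzyme MAOA (3.32 ± 0.17), the guidance factor SEMA5A (3.31 ± 0.14), the pentraxin PTX3 (3.31 ± 0.11), LRRN3 (3.31 ± 0.09), the lysophospholipase D ENPP2 (3.30 ± 0.33), SAMD11 (3.29 ± 0.30), the extracellular sulfatase SULF2 (3.24 ± 0.14) and the BMP inhibitor SMAD6 (3.21 ± 0.34) completed the 12 highest.

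Several of the shared genes with the lowest folds are known from neuroendocrine cells. The secretory granule proteins CHGA (mean -4.38 ± 0.28, BH-adjusted p = 8.54e-09) and CHGB (-4.99 ± 0.33) and the neuroendocrine transcription factor INSM1 (-3.96 ± 0.10) fell in every line. The proneural transcription factor NEUROG2 went from 120 ± 3.79 to means of at most 6.71 (mean fold -6.31 ± 0.44, BH-adjusted p = 2.28e-08). That highest NEUROG2 mean, in ER42, came from libraries at 15.8, 4.06 and 0.267 and was 2.16 without ER42 replicate 1. The imprinted chromosome 14 genes RTL1 (-5.84 ± 0.32) and DLK1 (-4.90 ± 0.38) fell as well, as did the activin subunit INHBA (-4.56 ± 0.18), SUSD2 (-4.05 ± 0.13) and TMEM229A (-3.94 ± 0.12). One library moved the size of some of these in ER42: without ER42 replicate 3, DLK1 in ER42 went from -1.92 to -1.21, SAMD11 in ER42 from 1.78 to 1.14 and SMAD6 in ER42 from 1.96 to 1.24.

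In all, 3542 genes were called with the same sign in all 5 lines, 1115 of them higher and 2427 lower. Of these, 123 and 268 were at least 2-fold higher or lower in every line, and 790 and 2265 were protein coding. The median absolute fold of the shared genes ranged from 0.546 in ER28 and 0.56 in ER42 to 0.789 in ER5. Under quantile normalisation the shared genes split into 1257 higher and 1601 lower, 44% higher in place of 31.5%, and 2361 of them were also shared without it. The 5 comparisons used the same 3 parental libraries. Between pairs of lines, folds correlated across genes with a mean r of 0.76 (0.62 to 0.88), where 20 simulations of unchanged lines gave 0.50. The simulations drew all 18 libraries, the parental ones included, around the parental means with independent noise for each gene. They held no drift of a line and no correlation between genes. They cannot show how much of the overlap comes from the 3 real parental libraries. The mean covariance was 0.365 where the simulations gave 0.0401. The simulations gave 0 shared genes, and independent lists of the observed sizes would share 25, with 5.19 higher and 19.8 lower. The 3 parental libraries are too few to be split, so part of the excess may come from them.

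**Figure D2:**
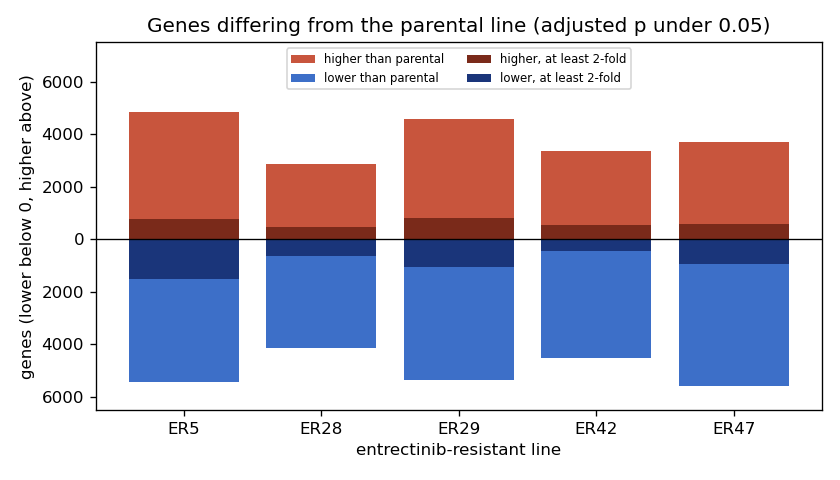
Number of genes called against the parental line in each resistant line (limma, adjusted p under 0.05), with higher genes above 0 and lower genes below, and darker bars for those at least 2-fold different. ER5 had 4854 higher and 5448 lower genes and ER28 had 2886 and 4135, an excess of lower genes that turned in both under quantile normalisation.

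Proliferation transcripts fell in the resistant lines. In the mean of the 5 lines, 25 of 26 tested cell cycle genes fell and 0 rose, the same adjusted over the list alone (median -0.93; camera, BH-adjusted p = 2.13e-10; adjusted p = 0.424 with an estimated correlation). The S-phase regulator E2F1 (-1.58 ± 0.10), the ribonucleotide reductase subunit RRM2 (-1.43 ± 0.16), the mitotic cyclin CCNB1 (-1.19 ± 0.12) and the mitotic kinase AURKA (-1.15 ± 0.12) had the largest folds, and 14 members fell in all 5 lines. Among MYC family genes and targets, 13 of 17 fell and 2 rose, the same adjusted over the list alone (median -0.53; camera, BH-adjusted p = 0.0031; adjusted p = 0.507 with an estimated correlation), and under quantile normalisation that list was not called (BH-adjusted p = 0.16, with 9.62e-06 to 0.507 over the alternatives). MYCN, the neuroblastoma oncogene, fell (-1.39 ± 0.15) while its relative MYC rose (1.13 ± 0.12), and the polyamine enzyme ODC1 fell (-0.83 ± 0.10). MYCN in ER42 went from -0.71 to -0.39 without ER42 replicate 3.

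Transcripts of glycolysis and of cholesterol biosynthesis fell. Of 24 hypoxia and glycolysis genes, 21 fell and 3 rose, the same adjusted over the list alone, and 19 fell in all 5 lines (median -0.99; camera, BH-adjusted p = 2.26e-08; adjusted p = 0.424 with an estimated correlation). Lactate dehydrogenase LDHA, which is also in the MYC list, went from 742 ± 10.4 to between 160 and 330 (-1.79 ± 0.09). The pyruvate dehydrogenase kinase PDK1 (-1.69 ± 0.12) and the angiogenic factor VEGFA (-1.57 ± 0.09) fell. The peptide hormone ADM rose (1.97 ± 0.22). Of 23 cholesterol biosynthesis genes, 22 fell and 0 rose, the same adjusted over the list alone, and 10 fell in all 5 lines (median -0.57; camera, BH-adjusted p = 1.82e-07; adjusted p = 0.424 with an estimated correlation). The sterol carrier STARD4 (-2.34 ± 0.11) and the enzymes EBP (-1.29 ± 0.07) and DHCR7 (-1.18 ± 0.08) were among the members with the largest folds. Cell cycle genes fell in the same lines.

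Stress response transcripts fell as well. Of 23 genes of the integrated stress and unfolded protein response, 16 fell and 2 rose, the same adjusted over the list alone (median -0.43; camera, BH-adjusted p = 0.000217; adjusted p = 0.504 with an estimated correlation). The endoplasmic reticulum chaperones HSPA5 (-1.44 ± 0.10), CALR (-1.12 ± 0.09) and PDIA4 (-1.10 ± 0.08) and the transcription factor ATF3 (-1.28 ± 0.14) led the list. Among immediate early and heat shock genes 9 of 18 fell and 0 rose, the same adjusted over the list alone, all 9 of them in all 5 lines (median -0.63; camera, BH-adjusted p = 0.0031; adjusted p = 0.502 with an estimated correlation). These included the chaperones HSPA1A (-1.68 ± 0.16), HSPA1B (-1.48 ± 0.16), HSPA8 (-1.42 ± 0.12) and HSPB1 (-1.32 ± 0.09). Without ER42 replicate 3, HSPA1B in ER42 went from -0.86 to -0.52. Lysosome genes had 11 of 23 members lower and 1 higher, the same adjusted over the list alone (median -0.20; camera, BH-adjusted p = 0.0415; adjusted p = 0.534 with an estimated correlation), with TFEB, a regulator of lysosome genes (-0.80 ± 0.10), ATP6V0D1 (-0.61 ± 0.07) and LAMP1 (-0.52 ± 0.05, or -0.32 under quantile normalisation for LAMP1 in the mean of 5 lines) among them. The lysosome call was lost at a filter of FPKM 5 (BH-adjusted p = 0.29), under quantile normalisation (0.439), with protein-coding genes only (0.255) and after removal of the GC and length trend (0.201), in a range of 0.00202 to 0.534. By line it was not called in ER5 (0.337), ER28 (0.215) or ER29 (0.557), but in ER28 it passed with no filter (0.0193, in a range of 0.0193 to 0.721).

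Transcripts downstream of ERK were mostly lower. Of 19 genes of ERK pathway output and feedback, 13 fell and 2 rose, the same adjusted over the list alone (median -0.65; camera, BH-adjusted p = 0.00173; adjusted p = 0.424 with an estimated correlation). PHLDA1 (-3.80 ± 0.13), the MAP kinase phosphatases DUSP5 (-2.23 ± 0.09) and DUSP4 (-1.89 ± 0.12) and the ETS factor ETV4 (-1.55 ± 0.12) had the largest folds. In ER28 that list was not called (camera, BH-adjusted p = 0.295), and ETV4 had a fold of 0.13 there. The RAS-ERK core itself had 4 of 22 genes higher and 11 lower, or 5 and 11 adjusted over the list alone, and was not called (camera, BH-adjusted p = 0.141). It was called with no filter (BH-adjusted p = 0.0102, with 0.0102 to 0.626 over the alternatives). HRAS (-0.83 ± 0.09) and the adaptor SHC2 (-0.74 ± 0.11) fell, and the adaptor GAB1 rose (0.67 ± 0.06).

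Other receptor tyrosine kinases moved mostly upward. Of 20 tested, 14 rose and 2 fell, or 14 and 3 adjusted over the list alone (median 0.57; camera, BH-adjusted p = 0.00187; adjusted p = 0.409 with an estimated correlation). KIT, the stem cell factor receptor, went from 0.769 ± 0.0727 to between 5.38 and 26.3 (2.89 ± 0.30), and FGFR2 (1.76 ± 0.11) and the collagen receptor DDR1 (0.88 ± 0.09) rose in all 5 lines, against the fall of RET. Eph receptors and ephrins had 3 of 12 higher and 4 lower, the same adjusted over the list alone, with EFNB2 (-2.95 ± 0.21), EFNA5 (-1.59 ± 0.11), EPHB2 (-0.98 ± 0.07) and EFNB1 (-0.58 ± 0.08) lowest, and the list was not called (camera, BH-adjusted p = 0.557).

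Most of the tested mesenchymal identity genes of neuroblastoma rose. The list held 24 genes, and those not tested lay below the filter. They included PRRX1 (listed at 0 in every library), RUNX1 (at most 0.464 FPKM in any library), YAP1 (at most 0.27) and WWTR1 (at most 0.822). Only 3 members rose in all 5 lines. Of 15 tested, 10 rose and 2 fell, the same adjusted over the list alone (median 0.60; camera, BH-adjusted p = 0.00191; adjusted p = 0.424 with an estimated correlation), led by the neural crest factors SOX9 (2.36 ± 0.18) and SNAI2 (2.33 ± 0.25), the AP-1 factor FOSL2 (2.04 ± 0.10) and the intermediate filament VIM (0.97 ± 0.10). VIM in ER5 had a fold of 0.30 and was not called. In ER42 the list was not called (camera, BH-adjusted p = 0.158), but passed with protein-coding genes only (0.0396) and after removal of the GC and length trend (0.0415), in a range of 0.0396 to 0.523. Noradrenergic identity genes went both ways, with 8 of 25 higher and 12 lower, the same adjusted over the list alone, and the list was not called (camera, BH-adjusted p = 0.368). Besides CHGA, CHGB and INSM1, the vesicular monoamine transporter SLC18A1 fell (-3.26 ± 0.11). Neuronal differentiation genes had 6 of 22 higher and 12 lower, the same adjusted over the list alone (median -0.51; camera, BH-adjusted p = 0.0507). The growth cone protein GAP43 (-2.89 ± 0.19), the secreted neuropeptide precursor VGF (-2.83 ± 0.27), the tubulin TUBB3 (-2.51 ± 0.18) and the RNA-binding protein ELAVL3 (-2.35 ± 0.23) fell most. That list passed with no filter (BH-adjusted p = 0.0024), at a filter of FPKM 5 (0.0409), under median-of-ratios scaling (0.0418) and under quantile normalisation (0.0404), in a range of 0.0024 to 0.513. By line it was called lower in ER5 (adjusted p = 0.424 with an estimated correlation), in ER28 (5 higher and 12 lower, the same adjusted over the list alone; 0.0415; adjusted p = 0.51 with an estimated correlation) and in ER29 (4 higher and 13 lower, or 5 and 13 adjusted over the list alone; 0.0371; adjusted p = 0.509 with an estimated correlation). It was called higher in ER42 (adjusted p = 0.513 with an estimated correlation), a call lost with a pseudocount of 0.1 (0.0564) and at a filter of FPKM 5 (0.0569), in a range of 0.00622 to 0.513. The ER28 and ER29 calls were lost with a pseudocount of 0.1 (0.0553 and 0.0525) and with protein-coding genes only (0.153 and 0.193), and that of ER29 after removal of the GC and length trend (0.0531), in ranges of 0.00262 to 0.51 and 0.00154 to 0.509.

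The remaining pathway lists were not called in the mean of the 5 lines. Apoptosis regulators had 5 of 21 higher and 11 lower, or 5 and 12 adjusted over the list alone (camera, BH-adjusted p = 0.589, direction down; median -0.24, mean 0.04). The survival factor BCL2 rose (2.62 ± 0.15), from 6.92 ± 0.60 to between 24.2 and 81.1, as did the pro-apoptotic BMF (2.62 ± 0.20), while the pro-apoptotic HRK (-2.16 ± 0.10) and BAK1 (-0.73 ± 0.08) fell. ABC efflux transporters had 3 of 11 higher and 3 lower, the same adjusted over the list alone (camera, BH-adjusted p = 0.62). The multidrug transporter ABCB1 fell in all 5 lines (-1.7 ± 0.17). So did ABCA3 (-1.14 ± 0.08) and ABCG1 (-0.70 ± 0.09). ABCC6 had a fold of 0.28 ± 0.10 (BH-adjusted p = 0.033). ABCC6 in the mean of 5 lines lost its call with no filter (0.0541), under quantile normalisation (fold 0.13) and without parental replicate 1 (0.0532) or parental replicate 2 (fold 0.18), in a range of adjusted p from 0.0054 to 0.313. Extracellular matrix genes had 9 of 20 higher and 5 lower, the same adjusted over the list alone (camera, BH-adjusted p = 0.461, direction up; median 0.17, mean -0.04), with TIMP3 (-2.98 ± 0.24), LAMA4 (-2.19 ± 0.13) and LOX (-1.22 ± 0.09) lower and BGN (1.26 ± 0.15) higher. Notch pathway genes had 9 of 15 higher and 5 lower, or 10 and 5 adjusted over the list alone (camera, BH-adjusted p = 0.252, direction up; median 0.43, mean -0.10), with HES6 lower (-2.76 ± 0.14) and HES1 (1.92 ± 0.50) and LFNG (1.09 ± 0.22) higher. The HES1 mean fell from 7.63 to 1.35 FPKM in ER42 without ER42 replicate 3, and from 7.47 to 4.41 in ER47 without ER47 replicate 3. LFNG in ER42 had a fold of 0.86, which without ER42 replicate 3 was 0.52 (BH-adjusted p = 0.147, with 0.00365 to 0.147 over the alternatives).

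Wnt pathway genes had 11 of 23 higher and 4 lower, the same adjusted over the list alone (camera, BH-adjusted p = 0.141), with the antagonist DKK3 (-2.51 ± 0.07) and the receptor FZD6 (-0.76 ± 0.08) lower and LGR5 (0.88 ± 0.17) and DKK2 (0.81 ± 0.11) higher. Interferon response genes had 6 of 15 higher and 1 lower, or 5 and 1 adjusted over the list alone (camera, BH-adjusted p = 0.13), with IFITM2 (1.30 ± 0.10), STAT2 (0.62 ± 0.08), IFITM3 (0.59 ± 0.12) and HLA-C (0.57 ± 0.10) higher. Both lists passed with protein-coding genes only (BH-adjusted p = 0.0433 for Wnt and 0.0471 for interferon), and the interferon list passed with no filter (0.00698), in ranges of 0.0433 to 0.594 and 0.00698 to 0.504. By line, the Wnt list was called higher in ER28 (11 higher and 4 lower, or 12 and 4 adjusted over the list alone; camera, BH-adjusted p = 0.0215; adjusted p = 0.507 with an estimated correlation) and ER47 (8 higher and 3 lower, or 10 and 3 adjusted over the list alone; 0.0316; adjusted p = 0.509 with an estimated correlation). Both calls were lost under quantile normalisation (0.0727 and 0.086), in ranges of 0.01 to 0.507 and 0.0101 to 0.509. The interferon list was called higher in ER29 and ER47, both at adjusted p = 0.424 with an estimated correlation. That list held 29 genes, and those not tested lay below the filter. They included ISG15 (at most 0.742 FPKM in any library), IFIT3 (0.904), MX1 (0.284) and OAS3 (0.119), so these calls rest on the 15 tested members. The ER47 call was lost under quantile normalisation (0.0856, in a range of 0.00693 to 0.424). Mitochondrially encoded transcripts had 4 of 13 higher and 0 lower, or 3 and 0 adjusted over the list alone (camera, BH-adjusted p = 0.105), and passed at a filter of FPKM 5 (0.0409) and with protein-coding genes only (0.0395), in a range of 0.0395 to 0.741. By line the list was called higher in ER28 (6 of 13 higher, or 8 adjusted over the list alone; camera, BH-adjusted p = 0.00394; adjusted p = 0.529 with an estimated correlation), in ER29 (7 higher, or 8; 0.0153) and in ER42 (3 higher, or 0; 0.0152), the latter both at an adjusted p of 0.57 with an estimated correlation, and 0 members were called lower in these lines. All these calls were lost under quantile normalisation (0.721, 0.798 and 0.577, with the direction turned in ER29) and after removal of the GC and length trend (0.0673, 0.309 and 0.822). Their ranges were 0.00241 to 0.721, 0.00406 to 0.798 and 0.00248 to 0.822. Their folds were small and turned or shrank with the scaling. MT-ND1 had 0.48 ± 0.09 and MT-CO1 0.32 ± 0.10, and under quantile normalisation these were 0.05 for MT-ND1 in the mean of 5 lines and 0.12 for MT-CO1 in the mean of 5 lines. MT-CYB (0.22 ± 0.07) and MT-ND3 (0.20 ± 0.08) became -0.09 for MT-CYB in the mean of 5 lines and -0.10 for MT-ND3 in the mean of 5 lines.

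Markers of other cell types, apart from those of fibroblasts, mostly lay below the filter. Tested were 4 of 12 glial and Schwann cell precursor, 9 of 13 fibroblast, 2 of 10 endothelial and 1 of 12 leukocyte markers. Among those below the filter were SOX10 (at most 0.996 FPKM in any library), PECAM1 (listed at 0 in every library) and PTPRC (at most 0.157). The tested glial and fibroblast markers went both ways. Glial and Schwann cell precursor markers had 2 of 4 tested members higher and 1 lower, or 3 and 1 adjusted over the list alone (camera, BH-adjusted p = 0.54). NGFR, which is also in the Trk list, rose, and PMP22 fell (-0.73 ± 0.10). Fibroblast markers had 5 of 9 higher and 2 lower, or 6 and 2 adjusted over the list alone (camera, BH-adjusted p = 0.269), with the collagens COL1A1 (1.58 ± 0.16) and COL3A1 (1.25 ± 0.15) higher and LUM (-1.80 ± 0.16) and THY1 (-0.73 ± 0.10) lower. COL3A1 in ER42 had a fold of -0.39, which was called without ER42 replicate 3 (-0.70, BH-adjusted p = 0.000781, with 0.000781 to 0.414 over the alternatives). Of the endothelial markers 0 rose and 1 of 2 fell, the same adjusted over the list alone (EGFL7, -0.99 ± 0.11), while CLDN5 had a fold of -0.20 ± 0.11 (camera, BH-adjusted p = 0.259). CLDN5 in the mean of 5 lines passed under quantile normalisation (-0.34, BH-adjusted p = 0.012, with 0.012 to 0.702 over the alternatives). The leukocyte list had 1 tested member, CD74, with 0 calls, the same adjusted over the list alone, at a fold of 0.14 ± 0.16 (camera, BH-adjusted p = 0.809).

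Of the 28 lists, 10 were called in the mean of the 5 lines with camera's preset correlation, and none held with an estimated correlation. For those 10 lists fry gave BH-adjusted p-values between 9.66e-08 and 0.00044. Fry also passed lists that camera did not call, so it does not single out those 10. Examples were the RAS-ERK core (fry, BH-adjusted p = 2.63e-06), Trk receptors and neurotrophins (3.42e-06), noradrenergic identity (4.76e-06) and ABC efflux transporters (2.46e-05). Extracellular matrix did not pass (fry, BH-adjusted p = 0.921).

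**Figure D3:**
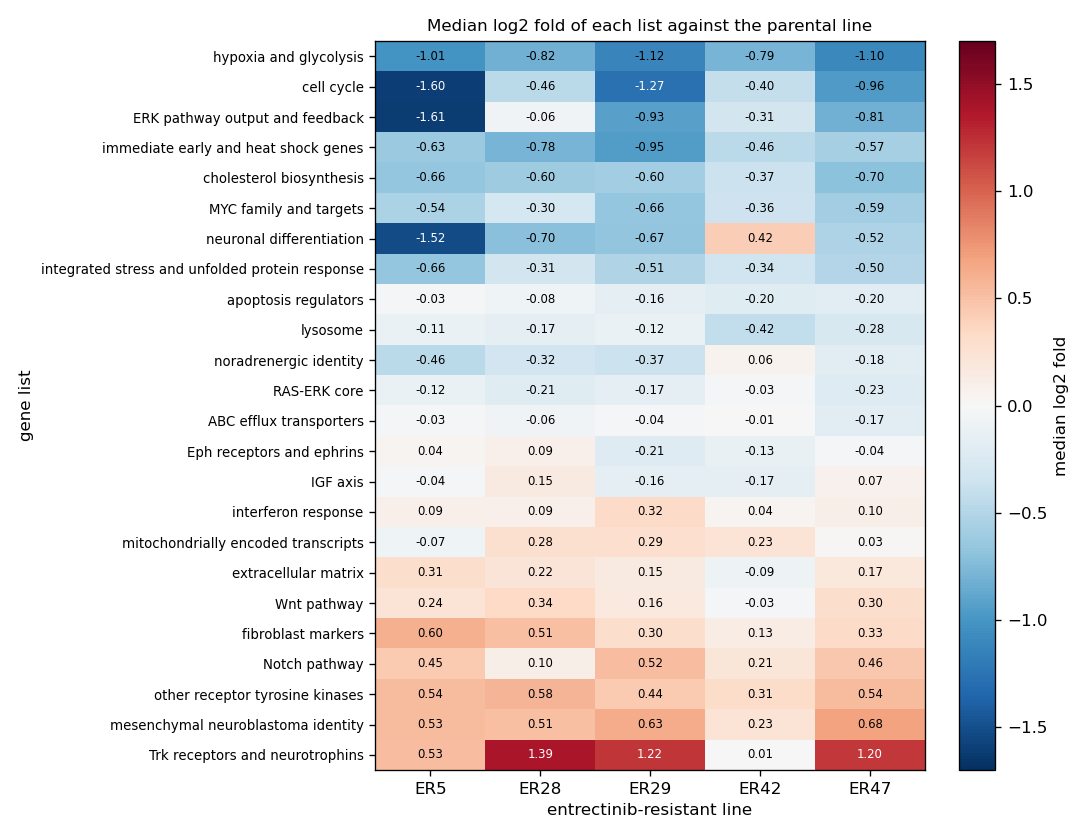
Median log2 fold against the parental line of each reported list with at least 5 tested members (vertical axis) in each resistant line (horizontal axis), with blue for lower and red for higher. Hypoxia and glycolysis ranged from -1.12 to -0.79, cell cycle from -1.60 to -0.40, and neuronal differentiation was at -1.52 in ER5 and 0.42 in ER42.

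Each resistant line was also described by itself, and its own genes were those that differed with the same sign from the parental line and from each of the other 4 lines. In ER5 the growth factor FGF7 rose from 0.179 ± 0.0445 to 33.0 ± 4.31 (4.84 ± 0.20, BH-adjusted p = 8.89e-11), the matrix protein ADAMTSL1 rose by 4.47 ± 0.31, GFRA2 rose by 6.38 ± 0.19, and TAFA3, listed at 0 in the 3 parental libraries, stood at 25.9, 23.4 and 15.7 in the 3 ER5 libraries. RTL1 (-8.42 ± 0.41), DLK1 (-7.78 ± 0.49) and the neuropeptide NPY (-5.97 ± 0.26) were lower there than in any other line. In ER5 4854 genes were higher and 5448 lower, or 52% of those tested, with 778 and 1501 at least 2-fold. Under quantile normalisation 5465 were higher and 4604 lower, 54.3% higher in place of 47.1%. Of the called genes, 598 higher and 745 lower genes were its own. Neuronal differentiation genes fell (4 higher and 14 lower of 22, or 5 and 14 adjusted over the list alone; camera, BH-adjusted p = 0.000503; adjusted p = 0.424 with an estimated correlation), and the cell cycle median was -1.60.

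In ER28 the transcription regulators LMO4 (4.71 ± 0.20, BH-adjusted p = 3.06e-10) and MSX2 (4.29 ± 0.26), the junction protein CGNL1 (4.22 ± 0.23) and the TGF-beta pseudoreceptor BAMBI (3.78 ± 0.30) were higher than in the other lines. The hypoxia-inducible factor EPAS1 went from 51.5 ± 0.296 to 2.28 ± 0.143 (-4.00 ± 0.17, BH-adjusted p = 2.85e-10). ARHGAP36 (-3.37 ± 0.18), the vesicle GTPase RAB27B (-3.04 ± 0.33) and the receptor modifier RAMP1 (-2.83 ± 0.20) fell. In ER28 2886 genes were higher and 4135 lower (35.5%), with 459 and 627 at least 2-fold, and 301 and 103 were its own. Under quantile normalisation the split was 3242 and 3118, or 51% higher in place of 41.1%. MYCN (-0.30) and MYC (0.30) were not called in ER28.

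In ER29 the axon guidance protein NTNG1 (4.18 ± 0.16, BH-adjusted p = 7.93e-11), the sulfotransferase CHST15 (3.44 ± 0.18), the secreted chaperone CLU (3.15 ± 0.25) and the motor protein MYO10 (3.04 ± 0.12) rose above the other lines. CDCA7L (-1.93 ± 0.11), PDLIM1 (-1.74 ± 0.15), the phosphofructokinase PFKP (-1.73 ± 0.14) and the progenitor filament NES (-1.61 ± 0.18) fell below them. In ER29 4565 genes were higher and 5368 lower (50.2%), with 820 and 1054 at least 2-fold, and 120 and 58 were its own. Under quantile normalisation the split turned to 4616 and 4513, or 50.6% higher in place of 46%. The interferon list was called higher in ER29 (9 of 15 tested members higher and 1 lower, the same adjusted over the list alone; camera, BH-adjusted p = 0.0117; adjusted p = 0.424 with an estimated correlation). Members below the filter, such as ISG15 and MX1, were not tested.

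In ER42 neuronal differentiation genes rose as a list (11 higher and 4 lower of 22, the same adjusted over the list alone, median 0.42, camera, BH-adjusted p = 0.0475, adjusted p = 0.513 with an estimated correlation), and VGF (-0.15) and ELAVL3 (-0.35) were not called. The ER42 libraries disagreed in these 2 genes. In replicates 1, 2 and 3 VGF stood at 87, 76.2 and 24.9 (parental 59.2 to 62.5) and ELAVL3 at 64.3, 59.5 and 27.3 (parental 57.1 to 63.2). The list was not tested without replicate 3. The angiotensin receptor AGTR1 (2.57 ± 0.17, BH-adjusted p = 3.7e-08), the cytokine IL7 (2.41 ± 0.28), PHACTR1 (2.40 ± 0.22) and the synaptic scaffold SHANK1 (2.12 ± 0.24) rose above the other lines. PPP1R3B (-1.94 ± 0.15), PLEKHA6 (-1.66 ± 0.29), the transcription factor NFIA (-1.43 ± 0.11) and NINJ1 (-1.34 ± 0.14) fell below them. In ER42 3350 genes were higher and 4522 lower (39.8%), with 552 and 454 at least 2-fold, and 263 and 234 were its own. Lysosome genes fell (0 higher and 19 lower of 23, or 1 and 19 adjusted over the list alone; camera, BH-adjusted p = 3.36e-05; adjusted p = 0.424 with an estimated correlation). The noradrenergic list had a median of 0.06 and a mean of -0.25 and was not called in ER42. RAB27B in ER42 had a fold of -0.91, and it lost its call without ER42 replicate 3 (-0.39, BH-adjusted p = 0.198, with 0.00336 to 0.198 over the alternatives).

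ER47 had few genes of its own, 23 higher and 17 lower. GBP4, an interferon-inducible GTPase (2.51 ± 0.19, BH-adjusted p = 8.24e-08), CAPN6 (2.17 ± 0.12), the cancer-testis antigen MAGEA10 (1.45 ± 0.14) and RNF212 (1.26 FPKM) were higher than in the other lines. The desmosomal cadherin DSG2 (-1.63 ± 0.09), FBXO16 (-1 ± 0.17) and MICALL1 (-0.86 ± 0.08) were lower, as was the readthrough transcript ZFP91-CNTF (-1.87 ± 0.19), whose value is uncertain because it overlaps other genes. In ER47 3720 genes were higher and 5565 lower (46.9%), with 580 and 945 at least 2-fold. Under quantile normalisation that split was 4368 and 4297, or 50.4% higher in place of 40.1%. The interferon list was called higher in ER47 with 5 of 15 members higher, 0 lower and a median of 0.10, the same adjusted over the list alone (camera, BH-adjusted p = 0.0393; adjusted p = 0.424 with an estimated correlation). Under quantile normalisation that call was lost (0.0856, in a range of 0.00693 to 0.424).

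The resistant lines also differed from each other. IGF2 stood at 1.48 ± 0.937 in ER5 and 128 ± 103 in ER42 (78.1 without ER42 replicate 1), and CHGA at 19.0 ± 3.77 in ER28 and 354 ± 191 in ER42. By the F test among the 5 lines (limma, BH-adjusted), 10348 genes differed (52.3%), 2163 of them with a range of at least 2-fold, and 2337 (66%) of the 3542 shared genes were among them. At least 1 line called 14534 genes, and 749 were called higher in one line and lower in another. In pairwise contrasts, ER29 and ER47 differed in the fewest genes (1106) and ER5 and ER42 in the most (8375).

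No protein-coding gene was called between lines from mice dosed every 4 hours (3 lines) and every 6 hours (2 lines), and 860 of all genes had an unadjusted p under 0.05. The smallest BH-adjusted p in limma among protein-coding genes, 0.651, belonged to ENSG00000241489, which has no symbol in the annotation and is outside the rule for named genes. The 3 genes that the rule named by their p were the ganglioside synthase ST8SIA1, with a 4-hour minus 6-hour difference of 1.19 ± 0.22 (SE over lines), TUSC3 (0.76 ± 0.14) and NBL1 (-0.82 ± 0.16), each with a BH-adjusted p of 0.829 in limma. Only 3 genes were called, and they are named here, like ENSG00000241489, after their values were seen: ENSG00000239776 (BH-adjusted p = 0.0177), the mitochondrial transfer RNA MT-TP (BH-adjusted p = 0.0243) and the microRNA gene MIR4737 (BH-adjusted p = 0.0404), all of them in limma. Each of the 3 was listed at 0 in 9 of 9 libraries of the 4-hour lines, 4 of 6 of the 6-hour lines and 2 of 3 of the parental line. With 3 lines against 2, the simulated recovery of differences of 1 on the log2 scale was 5.97%.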

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

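The tests of parental cells in ER42 and of the dosing interval for the ER42 pattern were chosen only after the results were seen, and the latter replaced a comparison of slopes (ER47 minus ER28, 0.15, 0.12 to 0.17) after the values of its genes were seen. The splits of the samples were planned.

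ST8SIA1, a ganglioside synthase, drew attention because it was called higher in ER29 and lower in ER42, and because the difference between these 2 lines was called too. It stood at 2.46 ± 0.247 FPKM in the parental line, 3.68 ± 0.627 in ER29 and 0.499 ± 0.17 in ER42 (SD, n = 3), with log2 folds of 0.43 and -1.21. The difference between the lines was 1.64 (limma, BH-adjusted p = 1.21e-06). The call for ST8SIA1 in ER29 was lost without parental replicate 2 (0.37, BH-adjusted p = 0.0684), without ER29 replicate 3 (0.33, BH-adjusted p = 0.0841) and under quantile normalisation (0.26, BH-adjusted p = 0.141), and its adjusted p ranged from 0.00838 to 0.141 over the alternatives.

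ER42 kept part of some transcripts that the other 4 resistant lines lost, among them IGF2, CHGA, CHGB, DLK1 and RTL1. Each of these 5 was highest in ER42 replicate 1 and lowest in ER42 replicate 3. The folds of ER42 over the 3542 shared genes had a slope of 0.71 on the mean folds, where the other lines had 0.89 to 1.25. Parental cells in the ER42 cultures could leave such a residue, and they would hold every lost transcript at or above one common share of its parental level. Over 15 lost genes the residual shares ran from 0.772 to 50.6%, 0.177 to 36.8% and 0 to 11.5% in the 3 ER42 libraries. Shares over 10% were held by 7, 6 and 1 of the 15 genes in ER42 replicates 1, 2 and 3, with median shares of 7.83, 3.25 and 1.74%. The highest ratio of the 25th to the 75th percentile of a library's shares was 0.179 (bootstrap interval over genes 0.0552 to 0.447). This argues against parental cells as the whole account. A first version of this test, with the median in place of the 75th percentile, had given 0.543 (0.124 to 0.911) and left the question open. In single genes, CHRM3 went from 87.9 to 1.62, 1.28 and 0.949 in the ER42 libraries while DLK1 went from 1150 to 585, 425 and 112. The dosing interval stays open, since 1 other 6-hour line cannot decide it: ER47 kept more than each 4-hour line in 6 of the 15 genes, IGF2, CHGA, CHGB and DLK1 among them, a share of 0.4 (0.133 to 0.667), while its slope over the shared genes, 1.04, lay above the 0.89 of ER28, a 4-hour line; a second population of resistant cells in ER42 stays open and untested.

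Regrouping the libraries gave the following. For each line against the parental line, the 10 splits of the 6 libraries are too few for a share under 0.05 (1 of 10 splits, the real one, reached the real count). The counts were 10302 in ER5 with 0 in the highest other split, 7021 in ER28 with 1, 9933 in ER29 with 1, 7872 in ER42 with 3 and 9285 in ER47 with 2. For genes shared by the 5 lines, 1 of 100 regroupings of the 18 libraries, the real one, gave as many as 3542. The highest other gave 2. For genes differing among the resistant lines, 1 of 100 regroupings of the 15 libraries gave as many as 10348, and the highest other gave 2656. Both regroupings moved single libraries and so mixed libraries of different lines, which raises the spread within groups. They show that libraries of a line resemble each other. They cannot tell whether lines would differ this much by chance, since whole lines were not regrouped and there is a single parental line. For the dosing intervals the 10 splits of the 5 lines are too few for a share under 0.05, with 3 genes in the real split and 2 in the highest other.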

How the results depend on the processing

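Of the counts of called genes, every one except that of the dosing intervals stayed within 1.5 times its value under each alternative other than the size limit. Leaving out each library in turn gave 9162 to 10378 genes for ER5, 5697 to 7340 for ER28, 8510 to 10210 for ER29, 6118 to 8306 for ER42, 8062 to 9569 for ER47, 2782 to 3575 shared by the 5 lines, 9069 to 10888 differing among them and 0 to 3 for the dosing intervals. The other alternatives gave 8119 to 10744, 5941 to 7382, 7761 to 10528, 6417 to 8090, 7524 to 9483, 2858 to 3640 and 8348 to 10493. An absolute log2 fold of at least 1, fewer genes by construction, left 2279 in ER5, 1086 in ER28, 1874 in ER29, 1006 in ER42, 1525 in ER47, 391 shared and 2163 differing among lines. The dosing intervals gave 0 genes with a pseudocount of 0.1, at a filter of FPKM 5, with protein-coding genes only and after removal of the GC and length trend, 18 with no filter, and 1 with line as a random block (correlation 0.463). The filter of FPKM 5 and the restriction to protein-coding genes remove low and noncoding genes by construction, and the cause of the other differences was not tested.

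With an estimated correlation in camera no list call held: the adjusted p was 0.409 for other receptor tyrosine kinases, 0.424 for ERK output, mesenchymal identity, cell cycle, hypoxia and glycolysis, and cholesterol biosynthesis, 0.502 for immediate early and heat shock genes, 0.504 for the stress response, 0.507 for MYC and 0.534 for lysosome. Lists crossed the threshold (adjusted p) as follows, and the cause was not tested. With no filter they were RAS-ERK core 0.0102, neuronal differentiation 0.0024 and interferon 0.00698. At FPKM 5 they were neuronal differentiation 0.0409, mitochondrial transcripts 0.0409 and lysosome, lost, 0.29. Neuronal differentiation had 0.0418 under median-of-ratios and 0.0404 under quantile scaling, where MYC (0.16) and lysosome (0.439) were lost. With protein-coding genes only, interferon (0.0471), Wnt (0.0433) and mitochondrial transcripts (0.0395) passed and lysosome was lost (0.255), as it was after removal of the GC and length trend (0.201).

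Quantile normalisation reversed MT-ND1 in ER5 (-0.42), MT-CYB in ER5 (-0.54), MT-CYB in ER29 (-0.01), MT-CYB in ER47 (-0.26), MT-CYB in the mean of 5 lines (-0.09), MT-ND3 in ER5 (-0.63), MT-ND3 in the mean of 5 lines (-0.10), NTRK2 in ER47 (0.33) and the gene list: mitochondrially encoded transcripts in ER29 (adjusted p 0.798) and gene list: mitochondrially encoded transcripts in ER47 (adjusted p 0.0178). Removal of the GC and length trend reversed MT-ND3 in ER42 (-0.19) and MT-ND3 in the mean of 5 lines (-0.05). The cause was not tested. Of the other values of the 164 named genes, 27669 were the same, 508 lost and 91 gained a call. No scaling moved the median of all genes by over 0.1.

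Libraries with the same replicate number did not deviate together (mean r 0.017 over 45 pairs, -0.263 to 0.23, against -0.008 over 90 other pairs), and 4 of 18 libraries matched their own number best. The replicate block gave 10430, 7159, 10038, 8090 and 9406 genes for ER5, ER28, ER29, ER42 and ER47, 3640 shared and 10457 differing among lines. Depth could be judged only relative to one library, and changes of low genes are the least certain.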

Other observations

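The tests of library scaling, lower cell cycle activity and gene order were chosen only after the results were seen, whereas the tests of GC content and length and of copy number were written before their results. The division of the first pair by list, the use of 2 lines in place of ER42 alone in the cell cycle test (made once the ratios of both lines were known), a looser bound for the scaling test (-0.3 in place of -0.5), and the removal from the copy number test of a window shared by 2 lines, came later. Every bootstrap interval, here and for ER42, resampled genes and not libraries or lines. It shows the spread among the genes used. Genes of a list moved together (estimated correlations of 0.359 for glycolysis and 0.505 for cholesterol biosynthesis), so these intervals are too narrow as uncertainty. What they argue against is limited to these genes in these libraries. The genes of the first paragraph were chosen after their values were seen.

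Single imprinted genes beside those already named were looked at, with no test of imprinted genes as a group. H19, the noncoding neighbour of IGF2 on chromosome 11, went from 6664 FPKM in the parental line to 29.4 in ER5, 163 in ER28, 165 in ER29, 1154 in ER42 and 288 in ER47 (mean fold -5.16 ± 0.29, limma, BH-adjusted p = 2.41e-09, called lower in 5 of 5 lines), and CDKN1C, also on chromosome 11, had a mean fold of -0.87. On chromosome 14, where DLK1 and RTL1 lie, the deiodinase DIO3 (-3.04 ± 0.12, BH-adjusted p = 3.8e-11) and the noncoding MEG8 (-1.21 ± 0.23, BH-adjusted p = 0.000374) fell, although MEG8 was not called in ER42. On other chromosomes PLAGL1 had a mean fold of 0.96 and PEG10 was at -1.28 in ER5, 2.73 in ER28 and 1.12 in ER42. GATA3, a transcription factor of sympathetic neuroblasts, rose by 2.33 ± 0.06 (BH-adjusted p = 1.23e-12), and HAND2, another, had a fold of 0.03 (BH-adjusted p = 0.732).

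Of 24 hypoxia and glycolysis genes 19, and of 23 cholesterol biosynthesis genes 10, were called lower in all 5 resistant lines, with list medians of -0.99 and -0.57 and list calls that were both lost at adjusted p = 0.424 with an estimated correlation. A bias by GC content and length was argued against, since the median over the 47 members after its removal was -0.66 (bootstrap interval -0.84 to -0.53). The higher of the medians under median-of-ratios and quantile scaling was -0.84 (-1.02 to -0.67) for glycolysis, which argues against library scaling there. For cholesterol biosynthesis it was -0.47 (-0.49 to -0.38), which passes only the looser bound of -0.3. Under the first bound of -0.5 library scaling stays open for cholesterol biosynthesis. That list stayed called under both scalings (camera, BH-adjusted p = 1.5e-07 and 5.47e-07, with 4.45e-13 to 0.424 over the alternatives). Lower cell cycle activity as the whole cause was argued against too: over ER42 and ER28, where the cell cycle list had medians of -0.40 and -0.46, the folds were 0.811 (0.669 to 1.02) of those in ER5, where it was -1.60, for glycolysis, and 0.715 (0.565 to 0.945) for cholesterol biosynthesis. By line the cholesterol ratio was 0.906 (0.742 to 1.21) in ER28 and 0.555 (0.283 to 0.877) in ER42, which alone would leave the question open. Entrectinib, passage through a mouse and culture history stay open and untested, and that resistant cells lowered these pathways may be put only as a hypothesis.

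In windows of 41 genes along the chromosomes, over 10485 genes, blocks of neighbouring genes were shifted in a line relative to the other lines, and 22 lay beyond the highest window median of 1000 random gene orders (0.29); 0.001 is the smallest share these orders can give, which argues against chance order. Of the 22, 2 shared a window on chromosome 6, from MBOAT1 to H3C12, higher in ER42 (0.43, but -0.13 against the parental line) and lower in ER29 (-0.33), so that window belongs to no single line. The strongest were in ER42 on chromosome 5 from HIGD2A to RNF130 (-0.82) and on chromosome 3 from EHHADH to LRCH3 (0.56), in ER5 on chromosome 2 from SH3YL1 to GEN1 (-0.57), and in ER28 on chromosome 1 from PRKAB2 to PI4KB (0.57). All blocks of ER28 lay on chromosome 1 and were higher, and all blocks of ER5 lay on chromosome 2 and were lower. The 22 blocks are therefore not a count of separate events. GC content and length were argued against, since the largest block kept 0.985 of its size after their removal (0.922 to 1.02). A change of copy number of the segment in that line is a candidate explanation: of 147 low genes in the 20 blocks of 1 line only that were not used to find them, 114 lay on the side of their block, a share of 0.776 (0.707 to 0.837), but copy number itself was not measured here and regional regulation stays open, untested.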
